A study of Rattus norvegicus with 6 samples.

How the data were processed

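RNA was measured by sequencing in retinas of wild-type BN rats, a pigmented inbred strain, after an injection into the vitreous of the eye. The injection was 2 µL of either saline or DMP, a cationic micelle named in the labels only by this code and given at 10 mg/mL in water. The vehicle thus differed between the groups, so an effect of the micelle cannot be told apart from that of its vehicle. Each group had 3 libraries, and the labels number those of both groups 30, 31 and 33 without saying what a number marks. The labels do not say whether the libraries came from separate animals, so p-values measure only the spread between these samples, which may be technical. The time between injection and collection is not given in the sources used here, nor is whether the eyes had also been injured by laser. Per the labels' protocols, polyadenylated RNA was selected with oligo(dT) beads, fragmented, copied with dUTP in the second strand so that strand was kept, and amplified by PCR without molecular identifiers being mentioned. Reads copied by PCR from a single fragment therefore could not be told apart. Intervals cover the spread between libraries, including what amplification added to it, but not a bias of amplification shared by all libraries.

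The authors' deposited count table held whole-number values for 34335 genes and 6 libraries, with no unit conversion stated. These were treated as estimated counts (expected counts already rounded in the deposited table), since low values did not behave as plain read counts. In each library between 673 and 741 genes had a count of 4, against 301 to 325 genes at 3 and 218 to 254 genes at 5. A value of 4 may therefore stand for about a single fragment, which makes genes with low counts less certain than their counts imply. A deposited table of FPKM values, computed by the authors, covered the 24744 genes with a count above 0 in any library, and the counts repeated in it differed from the count table for 0 genes. Reads were trimmed with cutadapt 1.9, quality was assessed with FastQC, and the genome build was mRatBN7.2, per the submitters' processing notes. The aligner and the counting tool are not given in the sources used here, nor is whether counting used strand. Coordinates are those of the authors' table on mRatBN7.2, and a RefSeq gene table of assembly GRCr8 served only for names and chromosome names. Of 830 list symbols, 825 matched the count table, 21 of them through a gene ID, an older name or an alias.

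Counts per library totalled 47842234 to 53255925. Genes were kept with the default filter of edgeR, a minimum count of 10 scaled to library size and a total of 15, which left 18571 genes. Normalisation used trimmed mean of M-values factors, and levels are given as CPM, counts divided by scaled library size. DMP was compared with saline by the two-sided quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3 on all 6 libraries with group as the only term. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. Standard errors were taken as the absolute log2 fold change divided by the square root of F, and intervals are at 95%. The biological coefficient of variation was 12.2%. Tested on simulated counts of 18284 genes with the means and library sizes of this comparison, the procedure recovered 68% of genes changed 1.5-fold, 92% of those changed 2-fold and 100% of those changed 3-fold, with 6 false calls among 200. Changed genes were drawn only from those with a mean of at least 1 CPM. The simulated values were plain counts without a library that stood apart, and the variability of each gene was set by its mean level alone. Recovery in the real data may therefore be lower, and the share of false calls may differ. Tyrp1, for example, fell from 24.4 to 7.56 CPM with an edgeR adjusted p of 0.13.

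Before the data were examined, 49 gene lists, the test designs, the alternatives and the rule for named genes were fixed. The lists covered retinal cell types, other tissues of the eye and blood that a dissection could carry in, and responses that an injection could bear on. Lists with at least 5 tested members, 47 in all, were tested with camera of limma 3.58.1 on voom log2 CPM values with a preset correlation of 0.01, Benjamini-Hochberg adjusted over lists. Camera asks whether the mean test statistic of the members of a list differs from that of the other genes. A few members with large changes can thus carry a call. Camera with a correlation estimated from the data and fry, a rotation test of a list by itself, were alternatives. For each list, members past the threshold were also counted with p-values adjusted over the list alone. A list score per library was the mean log2 CPM of tested members relative to the mean of the saline libraries.

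The rule named up to 12 genes per direction with the largest fold change among genes past the threshold. These needed a mean of at least 1 CPM, a gene symbol and no overlap between groups. Where fewer than 12 passed, all were named and then up to 6 of smallest unadjusted p, as values that did not pass. Up to 4 members of smallest p were added from each list past its threshold. Vegfa, Kdr, Flt1, Serpinf1, Ccl2, Il1b, Tnf, Gfap and Aif1 were named whatever their p, and some other genes that these rules name are not reported here. Other genes named below were chosen after their values were seen, among them list members that passed adjusted over the list alone.

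Alternatives were relative log expression factors, library size scaling, no filter, a stricter filter (10 counts in every library of a group and a mean of 1 CPM), the number as a replicate block, leaving out each library in turn, DESeq2 1.42.0, limma-voom, other thresholds, and limma with a trend on log2(FPKM + 1) or log2(FPKM + 0.1). The filtered FPKM versions kept genes with an FPKM of at least 1 in 3 libraries. Counts divided by 4 and rounded, and a robust quasi-likelihood fit, were added after seeing the data, as were 3 further gene lists (ciliary body and iris, resting microglia, pancreatic enzymes) and pathway sets named in the deposited table. Libraries were compared for repeats with a chi-square statistic over genes. Its lowest value for a pair, 10.7 per gene between saline 30 and saline 31, lay far above sampling noise, although values that are not plain counts inflate it, and all 6 libraries were counted separately. Figures were drawn with matplotlib 3.10.9.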

Results

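Retinal transcriptomes were compared between eyes injected with the cationic micelle DMP and eyes injected with saline, 3 libraries per group. The series title concerns suppression of choroidal neovascularization, the growth of choroidal vessels into the outer retina, and the comparison addressed which retinal transcripts differed after DMP. Total counts were 50900221, 53255925 and 52040377 in saline libraries 30, 31 and 33, and 52529314, 47842234 and 50989277 in DMP libraries 30, 31 and 33. Between 21124 and 21422 genes had a count above 0 per library. DMP library 30 stood apart from the others, at 53 on the leading principal component (28.1% of the variance), where the other 5 libraries lay between -23.4 and 7.0.

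After DMP, retinas held more transcript of some MHC class II genes, which encode the molecules that present antigen to helper T cells, with 2 of 9 past the threshold over all genes and 6 adjusted over the list alone. RT1-Da, an alpha chain of a rat class II molecule, rose from 4.77 ± 0.834 to 13.3 ± 2.54 CPM (mean ± SD, n = 3 per group), and RT1-Ba, the alpha chain of another, rose from 5.84 ± 0.851 to 14.3 ± 2.22 CPM. Rps27a, which encodes ubiquitin fused to a ribosomal protein, rose from 28.1 ± 7.33 to 68.1 ± 10.1 CPM. Mfrp, a frizzled-related membrane protein of the retinal pigment epithelium and ciliary epithelium, fell from 12.9 ± 4.54 to 3.73 ± 0.191 CPM. In camera with a preset correlation, lists of microglial, antigen presentation, complement and interferon genes were higher and lists of lens and fibroblast genes lower. Lists of retinal neurons, Müller glia and endothelium did not pass the test. With a correlation estimated from the data, 0 lists passed, and the lowest Benjamini-Hochberg adjusted p in camera was 0.26. That version may have too little power with 3 libraries per group to pass any list, so it does not decide whether these calls hold.

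These 4 genes were the ones past the threshold among 18571 tested with the quasi-likelihood test of edgeR, 3 higher and 1 lower. RT1-Da changed by 1.47 on the log2 scale (SE 0.168, Benjamini-Hochberg adjusted p = 0.0307), RT1-Ba by 1.29 (SE 0.15, adjusted p = 0.0307), Rps27a by 1.27 (SE 0.159, adjusted p = 0.031) and Mfrp by -1.78 (SE 0.215, adjusted p = 0.0307) in that edgeR test. For each of them all 3 DMP libraries lay on the same side of all 3 saline libraries. RT1-Da lies on chromosome 20 from 4513464 to 4518457 and RT1-Ba from 4575134 to 4579727 on the same chromosome. Rps27a lies on chromosome 14 from 103285734 to 103288011 and Mfrp on chromosome 8 from 44445636 to 44450859. RT1 genes form a multigene family and ribosomal protein genes have processed copies, so reads of RT1 genes and of Rps27a may be shared with near-identical sequences and their values are uncertain. At an unadjusted p under 0.05 there were 862 genes, 386 higher and 476 lower, where chance alone would give 929. Groups did not overlap for 1728 genes or 9.3%, where chance gives 10%. The number past the threshold was 92 with DESeq2, 4 with limma-voom and 45 in edgeR with the number as a replicate block. It was 0 without DMP 31 (834 at an unadjusted p under 0.05), 2 without saline 33, 9 without DMP 30 and 81 without DMP 33. All 4 calls were lost without DMP 31, where adjusted p in edgeR ran from 0.0513 for RT1-Ba to 0.13 for Mfrp, with log2 fold changes of 1.52 for RT1-Da, 1.42 for RT1-Ba, 1.39 for Rps27a and -1.75 for Mfrp. RT1-Da also lost its call without saline 30 (adjusted p = 0.0928) or saline 31 (0.105), RT1-Ba without saline 30 (0.0844), saline 31 (0.105) or saline 33 (0.0629), Rps27a without saline 30 (0.138) or saline 33 (0.092), and Mfrp without saline 33 (0.0701).

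**Figure D1:**
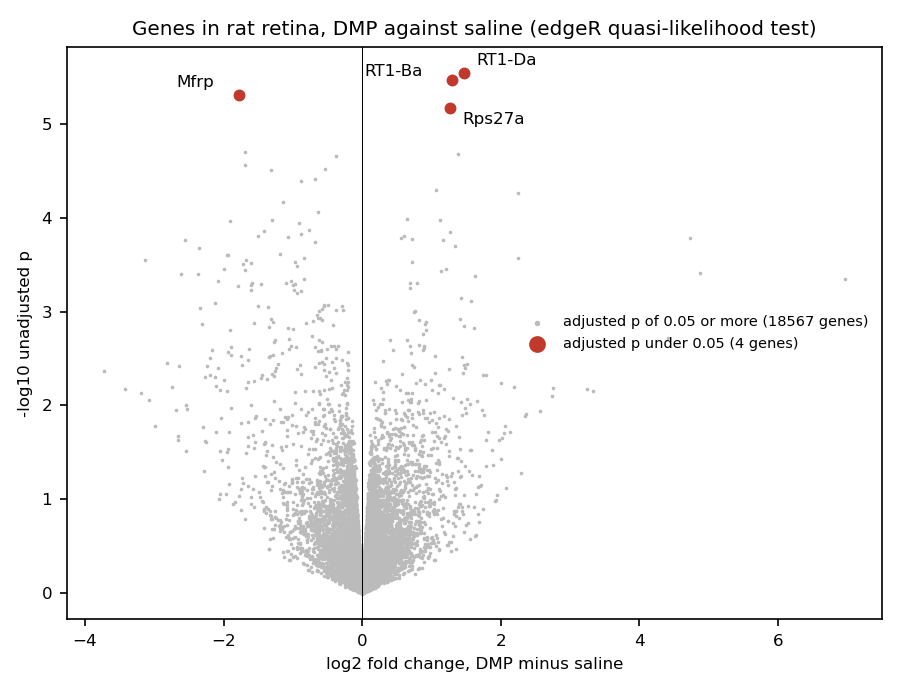
Each of 18571 genes is a point, with the fitted log2 fold change (DMP minus saline, 3 libraries each) on the horizontal axis and the negative log10 of the unadjusted p on the vertical axis. The 4 red points are genes with an adjusted p under 0.05 in edgeR, RT1-Da, RT1-Ba and Rps27a to the right and Mfrp to the left, and fitted values of genes without counts in a group, such as Ccl5, depend on the prior count.

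The genes next in order of p did not pass in edgeR, while all 12 of them passed with DESeq2. Without DMP 33, RT1-Db1 (adjusted p = 0.0308), RT1-Bb (0.026), S100a11 (0.0321), Vim (0.0141), Olfml1 (0.011), Efemp1 (0.00325), Nid2 (0.0169) and Lrp2 (0.00804) passed in edgeR. On the higher side they were RT1-Db1 (2.68 ± 0.595 against 6.96 ± 1.03 CPM in DMP), RT1-Bb (2.59 ± 0.284 against 5.45 ± 0.712), the class I heavy chain RT1-A1 (90.6 ± 12.9 against 142.1 ± 19.5), the class II invariant chain Cd74 (16.7 ± 4.63 against 36.2 ± 6.73), the NADPH oxidase subunit Cybb (1.26 ± 0.185 against 3.05 ± 0.592) and the lysosomal protease Ctss (31.8 ± 4.69 against 48.2 ± 4.63). Their adjusted p-values in edgeR ran from 0.0582 for RT1-Db1 to 0.0969 for RT1-A1, Cd74, Cybb and Ctss. On the lower side they were the calcium-binding S100a11 (log2 fold change -1.70), the intermediate filament Vim (-0.38), Olfml1 (-1.69), the matrix genes Efemp1 (-0.53) and Nid2 (-1.32), and the endocytic receptor Lrp2 (-0.68). The adjusted p in edgeR was 0.0582 for S100a11, Vim, Olfml1, Efemp1 and Nid2 and 0.0626 for Lrp2.

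**Figure D2:**
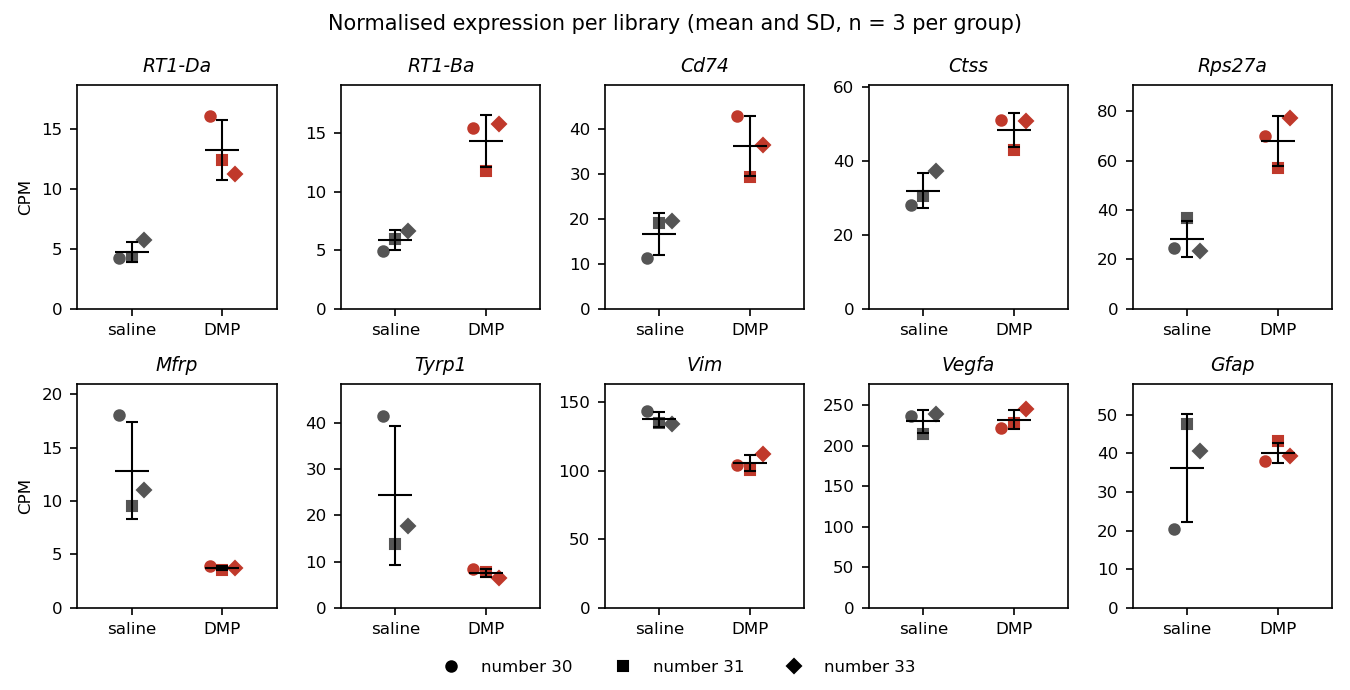
Normalised expression in CPM of 10 genes, with a point per library, horizontal bars for the mean and vertical bars for the SD (n = 3 per group). RT1-Da, RT1-Ba and Rps27a were higher and Mfrp lower in every DMP library than in every saline library, while the groups overlapped for Vegfa (230.0 ± 13.9 against 231.7 ± 11.9 CPM) and Gfap.

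Of the MHC class II list, 6 of 9 tested members rose adjusted over the list alone in edgeR, and 2 did so over all genes tested (6 with DESeq2, 2 with limma-voom). They were RT1-Da, RT1-Ba, RT1-Db1, RT1-Bb, Cd74 and RT1-DMb, the last at 3.34 ± 0.469 against 6.23 ± 1.83 CPM. Ciita, the transactivator of class II genes, was at 18.6 ± 2.21 CPM in saline and 18.4 ± 1.23 in DMP. The list was higher in camera (median log2 fold change 1.07, Benjamini-Hochberg adjusted p = 1.78e-13), with adjusted p = 0.26 with an estimated correlation. Of the MHC class I list, 8 of 18 rose adjusted over the list alone and 0 over all genes in edgeR (11 at an unadjusted p under 0.05, 2 with DESeq2, 0 with limma-voom). RT1-A2 was at 33.8 ± 3.48 against 55.9 ± 11.5 CPM, RT1-CE10 at 2.61 ± 0.264 against 4.80 ± 1.56, and B2m, the class I light chain, at 103.3 ± 27.9 against 153.7 ± 24.1. RT1-A1 and RT1-A2 overlap on the same strand of chromosome 20, which leaves the split of reads between them uncertain. The class I list had a median of 0.58 (camera adjusted p = 1.2e-14, and adjusted p = 0.306 with an estimated correlation), which was 0.26 without DMP 30.

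Of the microglia and macrophage list, 11 of 17 members rose adjusted over the list alone and 0 over all genes in edgeR (11 at an unadjusted p under 0.05, 4 with DESeq2, 0 with limma-voom). Among them were Ctss, the lysosomal glycoprotein Cd68 (1.97 ± 0.522 against 4.56 ± 0.995 CPM), the microglial marker Aif1 (2.89 ± 0.273 against 4.88 ± 0.755) and C1qc (8.51 ± 2.93 against 16.04 ± 3.08). The list median was 0.60 (camera adjusted p = 1.36e-18), with adjusted p = 0.281 with an estimated correlation. Of 18 complement genes, 6 rose adjusted over the list alone (C1qa, C1qb, C1qc, C2, C3 and C4a) and 0 over all genes in edgeR (8 at an unadjusted p under 0.05, 2 with DESeq2, 0 with limma-voom). C2 was at 13.2 ± 1.75 against 21.4 ± 4.47 CPM, C4a at 18.4 ± 3.53 against 31.04 ± 7.32, and C1qa at 13.5 ± 3.01 against 25.5 ± 8.32. The complement median was 0.46 (camera adjusted p = 3.92e-10, and adjusted p = 0.306 with an estimated correlation), 0.24 without DMP 30 and 0.22 without saline 30. The microglia and complement lists share C1qa, C1qb and C1qc.

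Of 24 type I interferon genes, which cells switch on in response to interferon, 15 rose adjusted over the list alone and 0 over all genes in edgeR (17 at an unadjusted p under 0.05, 1 with DESeq2, 0 with limma-voom). Rsad2 was at 2.96 ± 1.29 against 9.05 ± 5.11 CPM, Ifit3 at 1.02 ± 0.348 against 2.84 ± 1.71, Oas1b at 2.55 ± 1.11 against 10.2 ± 9.52 and Irf9 at 19.1 ± 1.92 against 31.2 ± 12.9. The list was higher in camera (median 0.94, adjusted p = 1.51e-13), with adjusted p = 0.424 with an estimated correlation, and its median was 0.37 without DMP 30. Its score was 1.79 in DMP 30, 0.79 in DMP 31 and 0.07 in DMP 33, against -0.33 to 0.50 in saline.

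The innate sensing and inflammasome list had a median of 0.52 over 17 members (camera adjusted p = 2.52e-05, and adjusted p = 0.324 with an estimated correlation), 0.35 without DMP 30 and 0.23 without saline 30. Adjusted over the list alone, 0 of its members passed in edgeR, as over all genes (5 at an unadjusted p under 0.05, 0 with DESeq2 and with limma-voom). Its members of smallest p were Tlr1 (0.923 ± 0.34 against 1.91 ± 0.21 CPM), Zbp1 (0.456 ± 0.103 against 1.30 ± 0.895), Nlrp3 and Tlr2. The necroptosis and pyroptosis list had a median of 0.35 over 10 members (camera adjusted p = 0.000349, and adjusted p = 0.26 with an estimated correlation), 0.15 without saline 30, and its call was lost with the stricter filter. In edgeR 0 of its members passed adjusted over the list alone or over all genes (1 at an unadjusted p under 0.05, 0 with DESeq2 and with limma-voom), and Ninj1, Casp12, Casp1 and Ripk3 had the smallest p. Ninj1 was at 12.97 ± 0.594 CPM in saline and 15.2 ± 0.232 in DMP, and Casp12, Casp1 and Ripk3 had means of at most 1.21 CPM in either group.

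Of 16 tested cytokines and chemokines, 1, Ccl5, rose adjusted over the list alone, and 0 over all genes in edgeR (1 at an unadjusted p under 0.05, 1 with DESeq2, 1 with limma-voom). Ccl5, which draws T cells and monocytes, had counts of 0 in each of the 3 saline libraries and of 18, 12 and 16 in the DMP libraries, close to the least that can be measured here. Cxcl10 was at 0.352 ± 0.112 against 1.06 ± 1.18 CPM, Tgfb1 at 2.66 ± 0.152 against 3.19 ± 0.467, and Il18 at 1.65 ± 0.217 against 2.04 ± 0.232. With Ccl5 placed at the bound that a floor of 3 counts over the saline group gives, the list median stayed at 0.25. A median hardly depends on how high 1 member lies, and camera was not rerun with that bound. The list, with a median of 0.25 and a mean of 0.765, was higher in camera (adjusted p = 0.018, and adjusted p = 0.335 with an estimated correlation). This call was lost without saline 30 (median 0.01, adjusted p = 0.317), saline 31 (adjusted p = 0.053) or DMP 30 (median 0.09, adjusted p = 0.0512), and with no filter or the stricter filter. Il1b was at 0.203 ± 0.212 CPM in saline and 0.307 ± 0.151 in DMP. Ccl2 (counts of 38, 6 and 4 against 18, 0 and 4) and Tnf (4, 14 and 0 against 11, 8 and 4) were too low to test.

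Markers of blood leukocytes were sparse. The infiltrating monocyte and neutrophil list did not pass (9 members, median 0.60, camera adjusted p = 0.0748), but passed upward without DMP 30 (adjusted p = 4.25e-05) and with the stricter filter (0.0131). Of its members Plac8 rose adjusted over the list alone, from 1.42 ± 0.394 to 3.94 ± 2.09 CPM. S100a8 and S100a9, abundant in neutrophils, had 0 counts in all 6 libraries. Of 19 lymphocyte genes 4 could be tested, too few for the list test with the default filter, and Cd4, also made by macrophages, rose adjusted over those 4 alone from 10.1 ± 0.154 to 14.8 ± 1.24 CPM. Where more members were kept, the lymphocyte list was higher in camera with no filter (adjusted p = 0.00476), without saline 30 (0.0123) or without saline 33 (0.0224), and did not pass without saline 31 (0.127) or DMP 30 (0.0782). Summed counts of the 19 genes were 793, 786 and 783 in saline and 1183, 905 and 1040 in DMP, of which Cd4 took 508, 549 and 517 and then 805, 637 and 804. Phagocyte activation genes did not move as a list (median -0.04 against a mean of 0.08 and a camera direction upward, adjusted p = 0.751), while 2 of 12, Axl (8.82 ± 1.43 to 14.5 ± 1.59 CPM) and Clec7a (0.706 ± 0.205 to 1.52 ± 0.425), rose adjusted over the list alone.

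**Figure D3:**
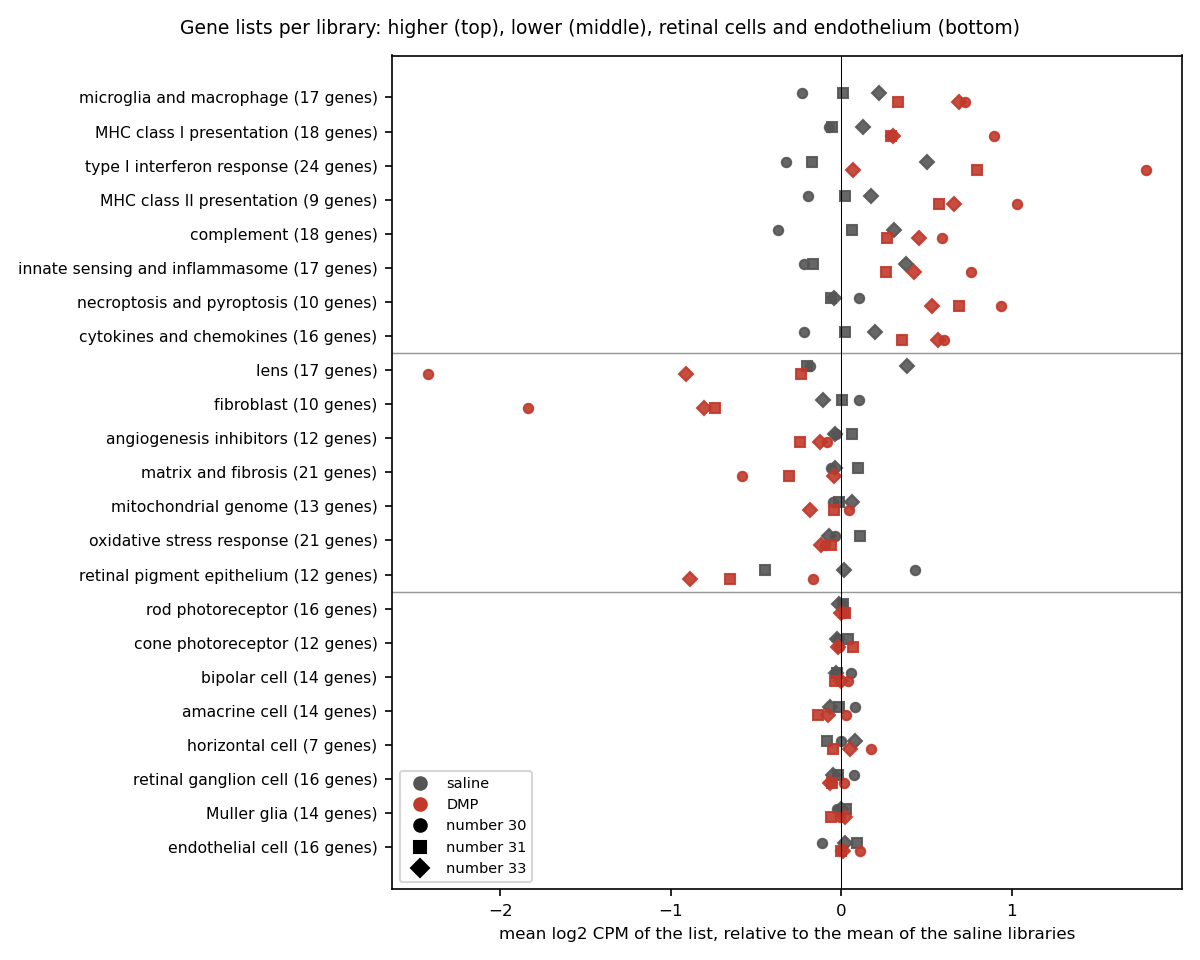
Mean log2 CPM of the tested members of each list relative to the mean of the saline libraries, with a point per library, for lists higher in camera (top), lists lower in camera (middle) and lists of retinal cells and endothelium (bottom). The MHC class II score lay between 0.57 and 1.03 in the DMP libraries and between -0.20 and 0.18 in the saline libraries, and DMP 30 lay farthest from saline for the interferon (1.79), lens (-2.42) and fibroblast (-1.84) lists.

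Some genes of tissues next to the retina fell. Of 10 fibroblast genes, 4 fell adjusted over the list alone and 0 over all genes in edgeR (5 at an unadjusted p under 0.05, 0 with DESeq2 and with limma-voom). These were the small proteoglycans Ogn (24.3 ± 7.22 to 7.98 ± 4.73 CPM), Fmod (27.0 ± 5.50 to 11.1 ± 6.17), Lum (5.63 ± 2.64 to 1.31 ± 1.21) and Dcn (2.04 ± 2.35 to 0.223 ± 0.212). The groups overlapped for Dcn, which was at 4.73 CPM in saline 30 but at 0.354 and 1.04 in saline 31 and 33. The list median was -0.95 (camera adjusted p = 1.02e-05, and adjusted p = 0.26 with an estimated correlation), -0.61 without DMP 30 and -0.17 without saline 31. Of 17 lens genes, 4 gamma crystallins fell adjusted over the list alone and 0 genes over all genes in edgeR (6 at an unadjusted p under 0.05, 1 with DESeq2, 0 with limma-voom). Crygd fell from 4.04 ± 1.81 to 0.929 ± 0.658 CPM and Crygb from 1.29 ± 0.293 to 0.206 ± 0.227, and Crygc and Cryge were the others. The gamma crystallin genes are near-identical neighbours, so their single values are uncertain. The lens median was -0.62 (camera adjusted p = 2.25e-08, and adjusted p = 0.306 with an estimated correlation), -0.30 without DMP 30, -0.22 without saline 33 and -2.04 without DMP 31. Summed over the 22 lens genes, CPM before scaling were 53.9, 56.5 and 86.6 in saline 30, 31 and 33 and 34.8, 80.8 and 44.2 in DMP 30, 31 and 33, so that DMP 31 lay within the saline range.

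Of 12 retinal pigment epithelium genes, 4 fell adjusted over the list alone and 0 over all genes in edgeR (4 at an unadjusted p under 0.05, 1 with DESeq2, 0 with limma-voom). All 4 act in melanin synthesis or the melanosome, Tyr (1.9 ± 1.294 to 0.218 ± 0.176 CPM), Tyrp1 (24.4 ± 15.0 to 7.56 ± 0.949), Pmel (19.4 ± 12.4 to 8.07 ± 3.81) and Mlana (1.26 ± 0.972 to 0.431 ± 0.0869), and are also made by other pigment cells. Saline 30 was the highest library for all 4 and carried much of their fall. Tyrp1 was at 41.6 CPM there against 13.9 and 17.6 in saline 31 and 33, and Pmel at 33.8 against 12.7 and 11.8. The groups overlapped for Pmel. Rpe65, the retinoid isomerase found in the pigment epithelium itself, was at 6.64 ± 2.23 against 8.95 ± 5.51 CPM, and Ttr at 17.7 ± 3.02 against 20.1 ± 11.1. The list was lower in camera (median -0.06, mean -0.60, adjusted p = 0.0186), with adjusted p = 0.785 with an estimated correlation. It was lost without DMP 31 (adjusted p = 0.0984) or DMP 33 (adjusted p = 0.293), and its median was -0.11, -0.25 and -0.40 without saline 30, 31 and 33 and -0.46, -0.16 and -0.33 without DMP 30, 31 and 33. DMP and saline libraries also differed in Rn18s, the 18S ribosomal RNA that oligo(dT) selection is meant to remove. It took 0.0439% to 0.1588% of counts in DMP libraries and 0.0121% to 0.0338% in saline libraries (log2 fold change 2.26, edgeR adjusted p = 0.12), beside every higher and lower list described here.

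The angiogenesis inhibitor list was lower (12 members, median -0.08, camera adjusted p = 0.00112, and adjusted p = 0.306 with an estimated correlation). In edgeR 3 of its members fell adjusted over the list alone and 0 over all genes (3 at an unadjusted p under 0.05, 1 with DESeq2, 0 with limma-voom). They were Col18a1, the collagen that yields endostatin (54.8 ± 6.60 to 36.7 ± 7.37 CPM), Thbs1 (6.18 ± 2.33 to 3.10 ± 0.356) and Timp3 (93.3 ± 6.05 to 80.0 ± 6.89). The median was -0.04 without DMP 31 and -0.13 without DMP 33. Of the 12 members 9 were below 0 and 3 above, among them Cxcl10 (0.352 ± 0.112 against 1.06 ± 1.18 CPM, with overlapping groups). Whether tissue from next to the retina carried the fall of this list was not tested. Serpinf1, which encodes the inhibitor PEDF, was at 1.02 ± 0.234 CPM in saline and 1.10 ± 0.298 in DMP. Angiogenic ligands and receptors did not pass as a list (23 members, median 0.01, camera adjusted p = 0.825). Vegfa had a log2 fold change of 0.01 (95% interval -0.12 to 0.14), its receptor gene Kdr one of 0.06 (-0.07 to 0.19) and Flt1 one of 0.01 (-0.20 to 0.22). Endothelial genes did not pass either (16 members, median 0.06, camera adjusted p = 0.393), except upward without saline 31 (0.0445).

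Smaller shifts were seen in 3 other lists, each a camera call in which 0 members passed in edgeR adjusted over the list alone or over all genes, and 0 with DESeq2 or limma-voom. Matrix and fibrosis genes were lower (21 members, median -0.12, adjusted p = 0.00349, and adjusted p = 0.281 with an estimated correlation; 3 lower and 1 higher at an unadjusted p under 0.05), with Mmp2 at 3.86 ± 0.239 against 2.80 ± 0.615 and Postn, the higher member, at 28.0 ± 1.78 against 31.9 ± 1.31. That call was lost without DMP 30 (median -0.08, camera adjusted p = 0.0632). Oxidative stress genes were lower (21 members, median -0.06, camera adjusted p = 0.0185, and adjusted p = 0.324 with an estimated correlation, 2 at an unadjusted p under 0.05), with Gpx3 at 35.1 ± 8.68 against 25.8 ± 2.04 CPM and Nqo1 at 3.44 ± 0.541 against 2.34 ± 0.223. Their call was lost without saline 31 (median -0.01, camera adjusted p = 0.448) or DMP 33 (adjusted p = 0.0597), and the median was -0.11 without saline 33. The 13 protein genes of the mitochondrial genome were lower (median -0.04, camera adjusted p = 0.0138, and adjusted p = 0.898 with an estimated correlation, 0 at an unadjusted p under 0.05), with ND5 at 2945 ± 219.9 against 2703 ± 216.8 CPM. Their call was lost without saline 33 (median -0.03, camera adjusted p = 0.595) or DMP 33 (median 0.01, adjusted p = 0.99), and the median was -0.10 without DMP 30, -0.07 without saline 30 or 31 and -0.05 without DMP 31.

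Lists of retinal cells did not pass in camera with all 6 libraries. Adjusted p-values were 0.624 for rod photoreceptors (16 members, median -0.001 with a mean of 0.01 and an upward direction), 0.823 for cones, 0.929 for bipolar cells, 0.17 for amacrine cells, 0.624 for ganglion cells and 0.825 for Müller glia. Horizontal cells had 0.978 (median 0.02 with a downward direction). The amacrine list passed downward without DMP 30 (camera adjusted p = 0.00626) or saline 33 (0.0252). Astrocyte genes did not pass (7 members, median 0.12 against a mean of -0.18 and a downward direction, camera adjusted p = 0.751). Among them Gja1, a gap junction gene, fell adjusted over the list alone from 60.0 ± 14.1 to 15.7 ± 10.2 CPM and S100b rose from 24.4 ± 0.142 to 28.2 ± 0.935. Gfap, a marker of reactive glia, was at 36.2 ± 14.1 against 40.1 ± 2.59 CPM. Reactive gliosis as a list had an adjusted p of 0.624 in camera, with Vim the member that fell adjusted over the list alone (137.3 ± 5.34 to 105.5 ± 5.94 CPM). That list passed downward without saline 30 (camera adjusted p = 0.0242) and upward without saline 31 (0.0158), so that single saline libraries decided its call and direction. The apoptosis list had a camera adjusted p of 0.929. The sign of the log2 fold change of Vegfa, Flt1, Serpinf1 and Gfap turned when single libraries were left out.

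The remaining lists did not pass in camera either. Adjusted p-values were 0.994 for lysosome genes, 0.396 for cholesterol biosynthesis, 0.393 for cholesterol efflux, 0.825 for NF-kB targets, 0.97 for endoplasmic reticulum stress, 0.732 for heat shock, 0.308 for immediate early genes, 0.935 for hypoxia and glycolysis, 0.694 for nuclear oxidative phosphorylation genes and 0.393 for the cell cycle. They were 0.393 for the visual cycle, 0.929 for synapse genes, 0.825 for the circadian clock, 0.308 for pericytes, 0.694 for oligodendrocytes, 0.393 for erythrocytes, 0.825 for surface epithelium and 0.17 for cytosolic ribosomal proteins. Median and mean differed in sign for cholesterol efflux, surface epithelium, lysosome, circadian clock and hypoxia genes, and median and direction for synapse genes, all with medians between -0.13 and 0.001. Of these, some passed in camera when a library was left out, ribosomal proteins upward without saline 31 (adjusted p = 3.77e-05) or DMP 33 (0.0419), erythrocytes downward without DMP 30 (0.00939) or saline 33 (0.00534), oxidative phosphorylation downward without saline 33 (0.00923) and the visual cycle upward without DMP 31 (0.0394). The ribosomal list, which does not hold Rps27a, had a median of 0.02 over 30 members. Of 5 Y-linked genes 3 could be tested, and Eif2s3y, Kdm5d and Uty had counts in all 6 libraries.

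Across the 15 list calls, 0 held with an estimated correlation, where the lowest adjusted p in camera was 0.26 (6 lists at an unadjusted p under 0.05). Estimated correlations were 0.823 for interferon, 0.691 for mitochondrial, 0.534 for MHC class I, 0.471 for microglia and 0.384 for MHC class II genes. These lie far above the preset 0.01, so the preset p-values of such lists are likely too small. In lists with little correlation among members, correlation does not account for the loss. The necroptosis and pyroptosis list had an estimated correlation of -0.016, below the preset 0.01. Its adjusted p in camera still went from 0.000349 to 0.26. The matrix and fibrosis list, at 0.012, went from 0.00349 to 0.281. This version may have too little power with 3 libraries per group to pass any list. By fry, a rotation test of each list by itself, 0 passed for a shift in a single direction and 2, MHC class II and cytokines, for change in either direction.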

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

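Counts divided by 4 and the robust fit were chosen only after the result was seen. The 4 genes past the threshold (3 higher, 1 lower) stayed past it with relative log expression factors, library size scaling, no filter and a fold limit. The stricter filter, which tested fewer genes, gave 12 (4 higher, 8 lower), DESeq2 gave 92 (35 and 57), DESeq2 with the replicate block 99 (21 and 78), counts divided by 4 gave 35 (11 and 24), and the robust fit 18 (5 and 13), the last with 3 of the 4. Limma-voom gave 4, all higher and 0 lower, 3 of them shared. Limma on FPKM gave 0 in all 3 versions (0 higher, 0 lower; 612, 605 and 1158 genes at an unadjusted p under 0.05), with smallest adjusted p-values of 0.0736, 0.0834 and 0.114. An adjusted p under 0.1 gave 33 (14 and 19), and an unadjusted p under 0.05 with a log2 fold change of at least 1 gave 255 (105 and 150). Leaving out single libraries gave 0 to 81 genes, 0 to 9 higher and 0 to 72 lower, with 0 without DMP 31 and 81 without DMP 33. Apart from the fewer genes or samples these choices leave, the cause was not tested. With the number as a replicate block edgeR gave 45 genes (8 higher, 37 lower), and 9 lists higher and 8 lower in camera, newly the infiltrating monocyte and neutrophil list upward (adjusted p = 0.00613) and the erythrocyte list downward (0.00571). Fibroblast genes Ogn (edgeR adjusted p = 0.0194) and Fmod (0.0295) and pigment genes Tyrp1 (0.0416) and Pmel (0.0122) then also passed over all genes. Of the 12 genes next in order of p, all passed with DESeq2, which made 30 false calls among 225 on simulated counts, RT1-Db1, S100a11, Vim, Olfml1, Efemp1, Nid2 and Lrp2 passed with the stricter filter, 11 passed with counts divided by 4, and 8 passed with the block (RT1-Db1, Ctss, S100a11, Vim, Olfml1, Efemp1, Nid2 and Lrp2), as did Rn18s (adjusted p = 3.99e-05), whose share of counts was lowest in library 30 and highest in library 33 of both groups. Deviations of same-numbered libraries correlated at 0.066, 0.035 and 0.028, against -0.079 to 0.046 for differently numbered ones, and 4 of 6 libraries correlated best with their own number. Whether the numbers pair the samples therefore stays open. The fit without the block was kept because the labels do not say what a number marks. Of the 4 genes, Mfrp kept its call in 11 of 14 alternatives, RT1-Da and Rps27a in 10 and RT1-Ba in 9, with adjusted p-values up to 0.395, 0.261, 0.279 and 0.239. Their log2 fold changes ran from -1.962 to -0.833 for Mfrp, 0.934 to 1.627 for RT1-Da, 1.153 to 1.506 for Rps27a and 0.994 to 1.416 for RT1-Ba, and the smallest for Mfrp, RT1-Da and RT1-Ba came from log2(FPKM + 1), where the added 1 shrinks folds of low values. For 4 genes that did not pass, the sign of the log2 fold change turned in single left-out runs, with ranges of -0.041 to 0.041 for Vegfa, -0.089 to 0.087 for Flt1, -0.117 to 0.274 for Serpinf1 and -0.138 to 0.392 for Gfap. Over the named genes reported here, 893 results stayed the same, 64 newly passed, 16 no longer passed and 7 changed sign. With an estimated correlation 0 lists were higher and 0 lower, and fry also gave 0 and 0. Lower lists numbered 4 to 9 and higher lists 8 to 10 when single libraries were left out. Counts that pile up at 4 limit what low genes such as Ccl5 can show.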

Other observations

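The runs without DMP 30 were planned, but the tests that apply criteria to them were chosen only after the result was seen, as were the tests of resting microglia, the added gene lists and the pathway sets, while the test of ciliary body and iris genes and the other groupings of the libraries were written before their values were known.

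Several transcripts outside the lists stood apart, all chosen after their values were seen. Slpi, a secreted protease inhibitor, was at 0.0385 ± 0.0666 CPM in saline and 1.09 ± 0.437 in DMP (n = 3 each, edgeR Benjamini-Hochberg adjusted p = 0.0969). Klrk1, the NKG2D receptor of natural killer and T cells, was at 0.0263 ± 0.0455 against 0.819 ± 0.574 CPM (edgeR adjusted p = 0.135), and neither passed. Rn18s was at 224.4 ± 108.8 against 1071 ± 579.9 CPM. Among 304 pathway sets named in the deposited table, 24 passed in camera with a preset correlation and 0 with an estimated one (lowest adjusted p 0.792). Antigen processing and presentation was higher (92 genes, median 0.05, camera adjusted p = 2.45e-05) and ECM-receptor interaction lower (109 genes, median -0.04, camera adjusted p = 0.0074). Of 10 transcripts of pancreatic digestive enzymes, Prss3, Cpb1, Pnliprp1 and Clps had counts in 5 libraries, for Prss3 1139, 1991 and 2334 in saline and 2038 and 1558 in DMP 31 and 33, and 0 in DMP 30. Prss1 had counts of 963 in saline 33 and of 806 and 737 in DMP 31 and 33, and 0 in saline 30, saline 31 and DMP 30. Summed over the 10 genes they made up 37.8 to 91.3 CPM before scaling in those 5 libraries and 5.24 in DMP 30.

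Of 9 MHC class II genes, 6 rose after DMP adjusted over the list alone and 2 over all genes, and the list call was lost with an estimated correlation (adjusted p = 0.26). A rise in DMP 30 alone is argued against, since without that library the list median was 0.966 and the scores of DMP 31 and DMP 33 (0.57 and 0.66) lay above the highest saline score (0.18) by more than the saline SD (0.19). A larger number of microglia of the resting type stays open as a candidate explanation of part of the rise. All 11 tested resting microglia genes, 5 of which the fixed microglia list also holds, had fold changes above 0, with a median of 0.296 and an upper quartile of 0.40, above the lower quartile of 0.17 of the 9 class II genes. That quartile lies among the class II members that did not rise, so the comparison could hardly go against this explanation. The median of the class II list was 1.07, above the highest resting microglia gene, Selplg at 0.794. The 6 class II genes that rose had a median of 1.21 and a lower quartile of 1.08, but they are the top of that list and exclude nothing. A response of these cells to DMP or its vehicle also stays open and was not tested. Which cells held the class II transcripts was not measured, so cells other than microglia stay open as their source.

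Of 10 fibroblast, 17 lens and 12 pigment epithelium genes, 4 each fell after DMP adjusted over the list alone and 0 over all genes in edgeR (5, 6 and 4 at an unadjusted p under 0.05, 0, 1 and 1 with DESeq2, 0 with limma-voom), and the list calls were lost with an estimated correlation (adjusted p = 0.26, 0.306 and 0.785). The ciliary body and iris, which border the retina at its rim, may have been carried into the DMP dissections less, while an effect of DMP or its vehicle on these tissues also stays open and was not tested. The fall of Mfrp, a gene of the pigment and ciliary epithelium, may share either cause, which was not tested. Neither cause was tested for the lower angiogenesis inhibitor and matrix lists. Of 14 tested genes from a list of 19 that left out genes already seen to fall, 11 were below 0 and 3 above, with a median of -0.523, which the explanation by dissection needs. The most abundant of them were Col9a1 (112.1 ± 16.6 against 61.0 ± 19.7 CPM), Aqp1 (83.8 ± 8.24 against 83.6 ± 4.18), Ptgds (72.8 ± 6.15 against 65.6 ± 9.003) and Ltbp2 (45.9 ± 8.98 against 12.4 ± 12.1), of which Aqp1 and Ptgds are also made in retina, and 0 are in a fixed list. The lists were lowest in different libraries, since the ciliary body and iris score was -0.92, -0.88 and -0.32 in DMP 30, 31 and 33 (saline -0.20 to 0.10), and the pigment epithelium score was -0.16, -0.65 and -0.89 (saline -0.45 to 0.43). A fall in DMP 30 alone is argued against for fibroblast genes, with a median of -0.61 without that library and scores of -0.74 and -0.81 in DMP 31 and DMP 33 against -0.11 to 0.11 in saline, but stays open for lens genes, with a median of -0.303 without it and a score in DMP 31 (-0.24) beside the lowest in saline (-0.20), although DMP 33 (-0.91) lay below it by more than the saline SD (0.33).

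Of 24 interferon genes, 15 rose after DMP adjusted over the list alone and 0 over all genes in edgeR (17 at an unadjusted p under 0.05, 1 with DESeq2, 0 with limma-voom), and the list call was lost with an estimated correlation (adjusted p = 0.424). A rise in DMP 30 alone stays open, since the median was 0.369 without that library, against 0.94 with it, and the score of DMP 33 (0.07) lay within the saline range of -0.33 to 0.50. The score of DMP 31 (0.79) exceeded the highest saline score by less than the saline SD (0.44), and what set DMP 30 apart was not tested. For the count of genes past the threshold, the 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 4 genes and the highest of the others 3, so that 1 split, the real one, gave as many. At an unadjusted p under 0.05, the split of saline 30, saline 31 and DMP 30 from the rest gave 2319 genes, against 862 for the real split. That of saline 30, saline 31 and DMP 33 gave 1016. The split with 2319 genes put DMP 31 and DMP 33 together with saline 33, so it partly overlaps with treatment. What divided the libraries in this way was not tested.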
